A study of Saccharomyces cerevisiae with 22 samples.

How the data were processed

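The series measured messenger RNA and ribosome-protected fragments in budding yeast, Saccharomyces cerevisiae, growing in glucose and 15 min after a move to medium without it. Per the labels, the strains were BY4741, a laboratory strain of the S288C background from which the reference genome was made, and EY0690, labelled as a w303 strain. Cultures grew at 30 °C in synthetic complete medium with glucose to an OD600 of 0.3 to 0.4, and every sample received 100 ug/ml cycloheximide, an inhibitor of translation elongation, for 1 min. Footprints are the pieces of mRNA that ribosomes shield from RNase I. Per the labels' protocols, monosomes were collected on a sucrose gradient or through a sucrose cushion, without saying which library had which, and the RNA libraries came from oligo-dT-selected polyA RNA, from total RNA or from RiboZero-depleted RNA, fragmented with alkali. The 22 samples fall into 14 groups of strain, kind of library and condition: 2 libraries per strain and condition for footprints and for polyA RNA, and 1 per condition for BY4741 total RNA, EY0690 total RNA and EY0690 RiboZero RNA.

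Reads were aligned with Bowtie 0.12.8 to genome build R64, per the submitters' processing notes. Which program counted the reads, which annotation it used, how it treated reads with several matches and the bounds of the regions counted are not given in the sources used here. The deposited table holds 5381 genes and, per the file headers, counts of reads in an initiation region and in the downstream region of each coding sequence, for 20 libraries. The counts are whole numbers. The authors' RPKM values equal the downstream count divided by the listed length and by the reads of both regions, within 2% for 100% of the genes checked in each library, and were used only for that check. The authors' log2 ratios in the same table were not used. For EY0690 the total and RiboZero RNA share 1 column per condition, which is the authors' pooled value, so it has no replicate and entered only alternatives named as such. The 2 initiation columns of that pooled RNA match no single sample and were not used. Blank count cells, 60 in the first starved BY4741 footprint library and 20 in starved BY4741 total RNA, all stood beside an RPKM of 0 and were read as 0. Of the table's identifiers, 5380 matched the R64 annotation, and the coordinates printed here are those of that annotation.

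Every test except the alternative with both regions summed used downstream counts, which leave out the start of the coding sequence, where cycloheximide lets ribosomes pile up. Downstream totals ran from 698310 counts in the second glucose EY0690 footprint library to 8110916 in the second glucose BY4741 footprint library. The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM scaling and Benjamini-Hochberg adjustment, and a gene passed at an adjusted p under 0.05. Genes needed at least 10 counts in at least 4 libraries of each kind. Changes are on the log2 scale with the tool's prior count, and the standard error (SE) printed is the size of the log2 change divided by the square root of the F value. CPM values (counts scaled to a common library size of 1e6) are TMM-scaled and given as mean ± SD over libraries. The polyA and footprint responses (starved over glucose) were each fitted over 8 libraries with strain as a covariate. Ribosome occupancy is footprints relative to polyA RNA, and its change is the assay by condition term of 1 model over 16 libraries with strain and strain by assay. Separate terms tested whether the response differed between strains, how the strains differed at both conditions together, and whether polyA selection changed the response relative to total RNA. That last test was planned over 12 libraries but used 10, because the EY0690 total RNA is held only in the pooled column. TMM assumes that most genes keep their share of the library, so a change is relative to the other mRNAs and says nothing about total mRNA or total translation per cell.

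The gene lists, the rule for named genes, the tests and most of the alternatives were fixed before the data were examined. The 20 lists tested were Hsf1 core targets, other heat shock genes, glycogen and trehalose metabolism, hexose uptake and phosphorylation, glycolysis and fermentation, gluconeogenesis and the glyoxylate cycle, the tricarboxylic acid (TCA) cycle, nuclear-encoded respiratory subunits, Msn2/Msn4 general stress genes, cytosolic ribosomal proteins, mitochondrial ribosomal proteins, ribosome biogenesis, translation factors, P-body and stress granule proteins, amino acid synthesis, the proteasome, endoplasmic reticulum (ER) chaperones, the cell cycle, histones and ergosterol synthesis. They were tested with camera of limma 3.58.1 at an inter-gene correlation of 0.01 and adjusted over the lists, and again with an estimated correlation and with fry. The rule named, for each response, the 5 largest rises and 5 largest falls among genes past the threshold, with a mean of at least 10 CPM and both starved libraries on the same side of both glucose libraries in each strain (for occupancy, the same sign in each strain), up to 2 members of each list by the same criteria, and 13 genes whatever their result: HSP30, HSP26, HSP104, SSA4, HSP12, GLC3, GSY1, GPH1, TSL1, HXK1, PGK1, CIT1 and RPL3. The strain comparisons used the 5 largest rises and falls. The heat shock lists were set against the glycogen and trehalose list by an exact two-sided permutation test of their mean log2 CPM (prior count 2), permuting condition within each strain and assay. Genes were marked as uncertain where at least 10% of the 28-base words of the coding sequence occur in another coding sequence, which held for 205 genes. The word length and that limit were set after the data had been seen.

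The mitochondrially encoded genes, HXT13, FBP1, ALD3 and the deleted marker genes LEU2, MET17 and URA3 are not analysed here, and HIS3, which BY4741 lacks only in part, checks nothing, so the strain labels could not be tested on markers. Replicates of a group differed by more than sampling noise, with a chi-square per degree of freedom of 5.09 to 124, so all were counted as separate. Nothing in the labels says that they came from separate cultures, and the p-values then measure only the spread between these samples, which may be technical. Glucose and starved libraries with the same number deviated together from their group means (Pearson's r across genes 0.15 in BY4741 and 0.31 in EY0690 for polyA RNA, 0.68 and 0.21 for footprints). All 4 lie above the 0.1 set as the bound, so the numbers were taken to pair the libraries, and the fit with the replicate number as a block stands beside a result wherever it changes a call or moves a count by over 1.5 times.

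The same code was tested on simulated counts drawn from the fitted means and library sizes, with 100 genes changed 2-fold and 100 changed 4-fold per comparison. For the polyA response edgeR recovered 88 and 100 of them among 5304 genes, for footprints 31 and 92 among 5018, for occupancy 16 and 84 among 5018, for the strain by condition term of polyA RNA 17 and 91 among 5304, for that of footprints 0 and 0 among 5018, for the strain difference 89 and 98 among 5304, and for polyA selection 2 and 41 among 5310. In that order its false calls numbered 7, 2, 4, 14, 0, 13 and 1. The simulated libraries were drawn independently, without the shared deviations of numbered pairs. Alternatives were DESeq2 1.42.0, RLE scaling, library size alone, TMM without ribosomal protein genes, no filter, at least 100 counts, voom, 1 strain alone, total RNA as the reference, the replicate block, and each library left out in turn. Added after the data had been seen were both regions summed, the pooled EY0690 RNA as a reference, and leaving out the BY4741 libraries numbered 2. Calculations also used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and matplotlib 3.10.9 drew the figures.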

Results

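The data collected are 8 ribosome footprint libraries, 8 polyA RNA libraries and 4 columns of other RNA from yeast with glucose and 15 min without it, in strains BY4741 and EY0690. Downstream counts came to 4085996 and 8110916 in the glucose and 1999970 and 4872124 in the starved BY4741 footprint libraries, and to 880315 and 698310 in the glucose and 1660505 and 1187135 in the starved EY0690 footprint libraries. The polyA libraries held 5742606, 7003745, 5252923 and 6038924 counts in BY4741 and 1974938, 1146371, 1774634 and 1311155 in EY0690, glucose before starved. BY4741 total RNA held 2181052 and 1585550, and the pooled EY0690 total and RiboZero RNA 3998151 and 2148397. The BY4741 footprint libraries numbered 2 stood apart from the other 6. Their log2 CPM correlated with that of the matching polyA library at 0.946 and 0.942 across genes, which are not independent replicates, against 0.820 to 0.873 in the others.

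**Figure D1:**
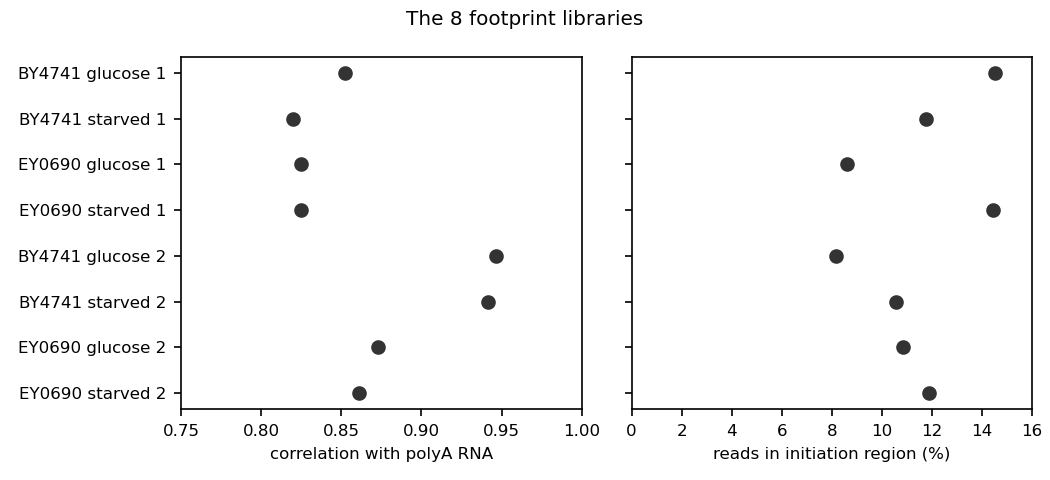
The 8 footprint libraries, with the Pearson correlation of log2 CPM with the polyA library of the same strain, condition and number (left) and the percentage of reads in the initiation region (right). The BY4741 libraries numbered 2 lie at 0.946 and 0.942 on the left, above the other 6, and the second glucose BY4741 library has the lowest initiation share, 8.16%.

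The first comparison asks which mRNAs changed in abundance within 15 min of glucose withdrawal. HSP30, which encodes a stress-induced plasma membrane protein (YCR021C, chromosome III, 156109 to 157107, 1 coding exon), went from 6.73 ± 3.79 CPM in glucose to 1586 ± 1165 CPM without it (SD, n = 4 each), a log2 change of 7.68 ± 0.48 (SE, edgeR adjusted p = 1.43e-07). The chaperone mRNAs HSP42 (5.59 ± 0.42), BTN2 (5.27 ± 0.43), HSP26 (5.04 ± 0.37), SSA4 (4.29 ± 0.47) and HSP104 (3.68 ± 0.27) and the membrane stress protein mRNA HSP12 (3.35 ± 0.17) rose with it. Of glycogen metabolism rose the mRNAs of GLC3, the branching enzyme (5.24 ± 0.21), GSY1, glycogen synthase (5.08 ± 0.37), GPH1, glycogen phosphorylase (5.06 ± 0.38), and GAC1, a regulatory subunit that directs a phosphatase to glycogen synthase (5.85 ± 0.37). The largest falls were in the cyclin PCL1 (-1.90 ± 0.44), the ribosomal protein genes RPL22B (-1.89 ± 0.25) and RPS28B (-1.81 ± 0.29), the repressor YHP1 (-1.78 ± 0.31) and HLR1 (-1.61 ± 0.35). The value for PCL1 joins strains that differed, with -0.77 in BY4741 and -3.67 in EY0690.

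Other large rises were YNL194C (7.53 ± 0.36) and TMA10, a ribosome-associated protein (7.08 ± 0.36). The hexose transporter HXT6 had 2 counts over the glucose libraries and 742 over the starved ones, a ratio of 426 (95% exact interval 117 to 3520), and YMR206W had 1 and 262, a ratio of 301 (53.5 to 11914). These intervals cover counting error only. HXT6 and HXT7 (5.39 ± 0.23) share 96.0% of their 28-base words, so their separate values are uncertain. Among the other genes named in every comparison, hexokinase HXK1 rose by 5.39 ± 0.35, trehalose synthase subunit TSL1 by 2.52 ± 0.22, phosphoglycerate kinase PGK1 by 1.06 ± 0.23 and citrate synthase CIT1 by 0.92 ± 0.16, while ribosomal protein gene RPL3 did not pass (0.32 ± 0.21, edgeR adjusted p = 0.246).

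Of 5304 genes tested, 1083 passed as higher and 1020 as lower, and with library size alone 879 and 1189. All 29 measured Msn2/Msn4 general stress genes rose (29 adjusted over the list alone), among them the stress gene DDR2 (5.11 ± 0.25). Of the glycogen and trehalose genes 17 of 20 rose and 3 did not pass (17 adjusted over the list alone). Of hexose uptake 12 of 17 rose (13), led after HXT6 by HXT7, and of gluconeogenesis and the glyoxylate cycle 13 of 16 rose (14), led by the lactate permease JEN1 (6.23 ± 0.38) and the activator CAT8 (4.09 ± 0.22). None of these 4 lists had a member that fell, and each was higher than other genes by camera (adjusted p = 5.98e-37, 2.36e-27, 1.37e-20 and 1.62e-10), also with an estimated correlation (adjusted p = 0.0028, 0.0057, 0.0028 and 0.0086).

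Of the Hsf1 core targets, chaperones under the heat shock factor, 16 of 18 rose (16 adjusted over the list alone), and of the other heat shock genes 11 of 15 (11). Camera placed both above other genes (adjusted p = 5.59e-12 and 2.34e-08), a call lost for each with an estimated correlation (adjusted p = 0.268 and 0.268). In the TCA cycle 13 of 16 rose (13), including SDH1 (1.93 ± 0.34), a subunit of succinate dehydrogenase, and the citrate synthase CIT3 (1.90 ± 0.28). In glycolysis 11 of 17 rose (12), led by TDH1 (4.12 ± 0.26) and ENO1 (2.93 ± 0.37), both uncertain because of paralogs, and 14 of 30 respiratory subunit genes rose (15), led by NDI1 (2.07 ± 0.15) and RIP1 (1.16 ± 0.17). Camera called these 3 lists (adjusted p = 4.76e-05, 0.00037 and 0.00053) and the call was lost with an estimated correlation (adjusted p = 0.171, 0.461 and 0.317).

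Ribosome biogenesis genes fell in 47 of 62 cases and rose in none (52 adjusted over the list alone), led by UTP15 (-1.32 ± 0.19) and RRS1 (-1.09 ± 0.19). Cytosolic ribosomal protein genes fell in 67 of 138 (72) with none higher. Cell cycle genes fell in 14 of 22 (15 lower and 1 higher, and 13 lower and 1 higher with the replicate block), led by PCL1 and the cyclin CLB6 (-1.41 ± 0.37). Camera called all 3 lower (adjusted p = 1.21e-10, 5.04e-09 and 0.00027), a call lost with an estimated correlation (adjusted p = 0.317, 0.385 and 0.423).

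Camera called none of the remaining 8 lists. Of the histone genes 5 of 10 fell and 1 rose (5 and 1 adjusted over the list alone), with HHF1 (-0.60 ± 0.18) and HHF2 (-0.65 ± 0.17) both uncertain. In BY4741 total RNA the change of HHF1 was 0.20. Translation factors had 7 of 32 lower and 2 higher (6 and 2), led by SUI1 (-1.08 ± 0.20) and NIP1 (-0.87 ± 0.16). Amino acid synthesis had 8 of 33 lower and 2 higher (2 and 1, and 7 and 6 with the replicate block), led by ILV5 (-1.36 ± 0.26) and HOM3 (-0.65 ± 0.16). P-body and stress granule genes had 5 of 20 higher and 1 lower (5 and 1), led by the decapping factors EDC2 (2.84-fold) and EDC1 (0.81 ± 0.18), and their median change turns from 0.10 to -0.01 when libraries are scaled by size alone, which moves the median of all genes from -0.03 to -0.13. ER chaperones had 5 of 14 higher (5), led by KAR2 (1.22 ± 0.26) and PDI1 (0.54 ± 0.18). Ergosterol synthesis had 2 of 22 higher and 5 lower (2 and 5), with ERG9 (0.57 ± 0.17) and HMG2 (0.54 ± 0.15) higher. The proteasome had 3 of 32 higher (0, and 8 with the replicate block), with PRE8 (0.54 ± 0.17) and RPN11 (0.52 ± 0.18), and mitochondrial ribosomal proteins 2 of 56 higher and 3 lower (2 and 0), with MRP8 (1.30 ± 0.17) and MRPS12 (0.75 ± 0.16). That last list was filled by gene symbol, so the membership of MRP8 rests on its name alone.

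In BY4741 alone 376 genes passed as higher and 5 as lower. BY4741 total RNA had 1 library per condition and so no spread of its own. Its response correlated with that of BY4741 polyA RNA at 0.842 across 5304 genes, and 77.6% had the same sign. Across 5024 genes the polyA responses of the strains correlated at 0.849, and 80.5% had the same sign.

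The second comparison asks how ribosome footprints changed. HSP30 footprints went from 5.73 ± 4.59 to 1491 ± 1457 CPM (n = 4 each), a log2 change of 7.77 ± 0.76 (SE, edgeR adjusted p = 0.00015), and TMA10 (7.58 ± 0.66), YNL194C (6.10 ± 0.54), ROQ1 (5.80 ± 0.70), ISF1 (5.59 ± 0.47) and BTN2 (5.46 ± 0.66) followed. The chaperones HSP26 (4.69 ± 0.54), SSA4 (3.66 ± 0.59) and HSP104 (3.46 ± 0.50) and HSP12 (3.27 ± 0.42) rose. HSP42 rose by 2.84 ± 0.40. Of the glycogen and trehalose genes GAC1 rose by 3.22 ± 0.29, the phosphoglucomutase PGM2 by 2.91 ± 0.47, GLC3 by 2.52 ± 0.30, GPH1 by 1.77 ± 0.29 and TSL1 by 1.56 ± 0.34, while GSY1 did not pass (2.84-fold, edgeR adjusted p = 0.0807, and 0.0187 with the replicate block). HXK1 rose by 2.33 ± 0.40. CIT1 (0.86 ± 0.29, adjusted p = 0.16 by edgeR, and 0.0387 with the block), PGK1 (0.76 ± 0.50) and RPL3 (0.12 ± 0.36) did not pass.

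Of 5018 genes tested, 147 passed as higher and 13 as lower. The 5 largest falls were PMP1, a small membrane protein (-2.73 ± 0.30), the ribosomal protein genes RPS8A (-1.96 ± 0.38), RPS8B (-1.49 ± 0.30) and RPS24B (-1.27 ± 0.29), and YCR043C (-1.40 ± 0.32). All of these except YCR043C are uncertain because of shared sequence. Of the genes that rose in footprints, 139 of 147 also rose in polyA RNA, where independent lists would share 29.8, and 10 of 13 that fell also fell, where they would share 2.55.

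Msn2/Msn4 general stress genes rose in 14 of 26 cases (22 adjusted over the list alone), led after TMA10 by the cell wall gene SPI1 (4.81 ± 0.59). Hexose uptake rose in 7 of 14 (10), led by MTH1 (3.81 ± 0.43) and the transporter HXT2 (3.14 ± 0.48), glycogen and trehalose in 7 of 19 (12, and 11 over all genes with the replicate block), gluconeogenesis in 5 of 12 (10), led by JEN1 (4.19 ± 0.60) and CAT8 (3.55 ± 0.49), Hsf1 targets in 8 of 18 (12), other heat shock genes in 5 of 15 (5) and glycolysis in 1 of 17 (1, and 3 with the block), the uncertain TDH1 (1.46 ± 0.35). Cytosolic ribosomal protein genes fell in 6 of 136 (7), and in 41 of 136 with the replicate block. Of the mitochondrial ribosomal proteins 0 of 56 passed in either direction (0), and with the block 1 rose and 1 fell. Camera called these 9 lists, the last 2 as lower (adjusted p = 8.39e-37, 6.28e-17, 7.41e-16, 6.84e-13, 5.83e-13, 8.83e-08, 0.0085, 6.44e-22 and 0.0129). Each call was lost with an estimated correlation (adjusted p = 0.0907, 0.0574, 0.103, 0.0574, 0.226, 0.319, 0.847, 0.198 and 0.847). Fry kept Msn2/Msn4, hexose uptake, glycogen and trehalose, and gluconeogenesis as higher, and cytosolic ribosomal proteins as lower (fry adjusted p from 0.0110 to 0.0133).

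The other 11 lists were not called. In them passed NDI1 (1.46 ± 0.24) and QCR8 (1.04 ± 0.24) of 30 respiratory subunit genes (7 higher and 1 lower adjusted over the list alone), the histone HTB1 (1.59 ± 0.33) of 10 (2 higher), EDC2 (2.61 ± 0.47) of 20 P-body and stress granule genes (1) and the proteasome subunit PRE2 (1.22 ± 0.29) of 32 (1). No member passed, over all genes or over the list alone, among 33 amino acid synthesis, 22 cell cycle, 14 ER chaperone, 22 ergosterol, 62 ribosome biogenesis, 16 TCA cycle and 32 translation factor genes. With the replicate block 6 respiratory subunit genes passed as higher and 1 as lower. Of the others 2 histones, 2 P-body and 3 proteasome genes passed as higher then, 1 each of the amino acid synthesis, ER chaperone and TCA cycle genes as higher, and 2 ribosome biogenesis genes and 1 translation factor gene as lower. The median and the mean of the ER chaperone, P-body, amino acid and ergosterol lists differ in sign, and the proteasome median turns from 0.00 to -0.13 with library size alone. That scaling moves the median change of all genes in footprints from -0.03 to -0.17.

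The starved BY4741 footprint library numbered 2 held less of the genes that rose than the other 3 starved libraries, for HSP30 92.4 CPM against 886, 3504 and 1482 CPM, and for HSP104 609 CPM against 3354, 6995 and 4771 CPM. Without it 333 genes passed as higher and 154 as lower, without both BY4741 footprint libraries numbered 2, an alternative chosen afterwards, 380 and 199, and with the replicate block 324 and 105. BY4741 alone gave 1 gene and EY0690 alone 427, and the total was 103 without the first glucose BY4741 library, 88 and 87 without the first and second glucose EY0690 libraries and 80 and 102 without the first and second starved ones.

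**Figure D2:**
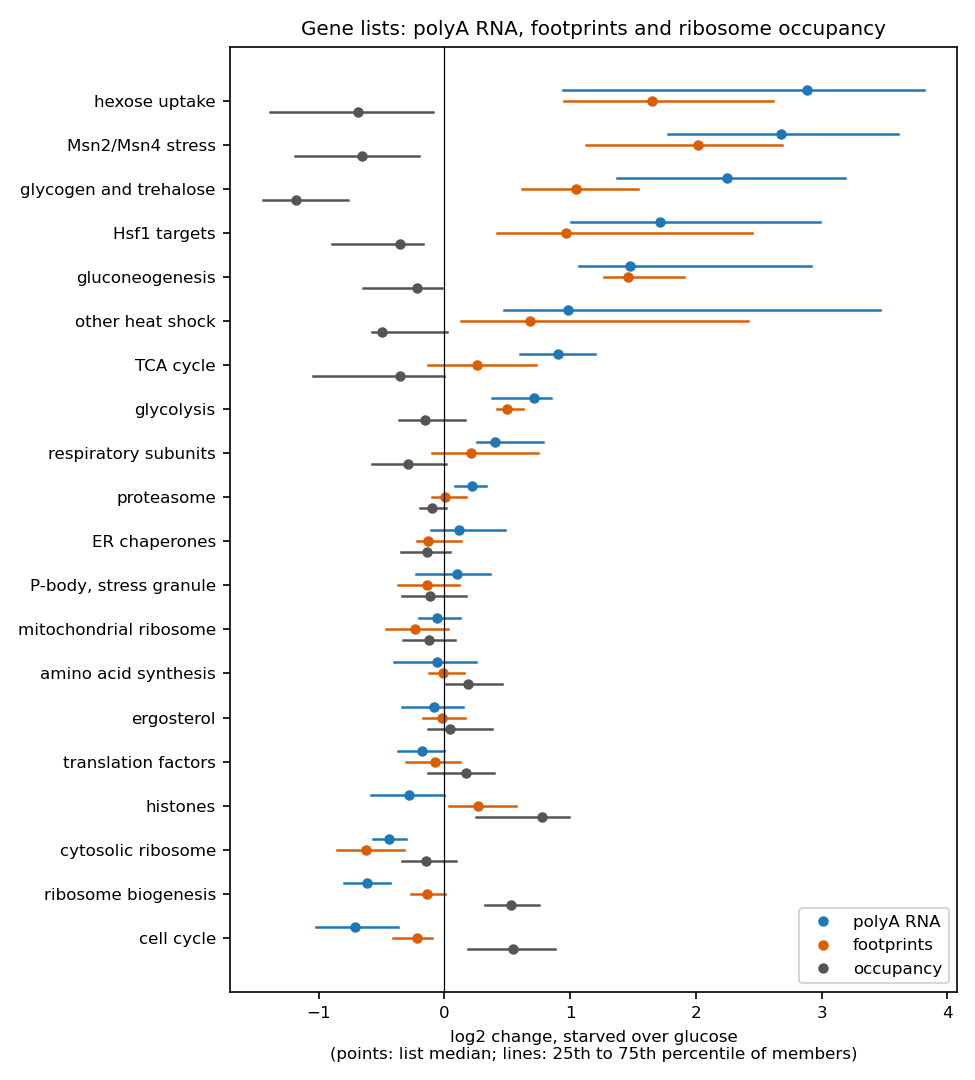
Median log2 change (points) of the 20 gene lists in polyA RNA, footprints and ribosome occupancy, with the 25th to 75th percentile of their members (lines). Glycogen and trehalose genes have a polyA median of 2.25, a footprint median of 1.04 and an occupancy median of -1.18. P-body (polyA), proteasome (footprints) and ergosterol (occupancy) medians change sign with library size alone.

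The third comparison asks whether ribosome footprints changed in proportion to the mRNA, as the ribosome occupancy of each gene. The glycogen genes GSY1 and GPH1 had the 2 largest losses. In the model over all 16 libraries GSY1 polyA RNA went from 27.6 ± 23.1 to 657 ± 210 CPM and its footprints from 38.5 ± 38.0 to 93.4 ± 90.9 CPM (SD, n = 4 each), an occupancy change of -3.51 ± 0.62 (SE, edgeR adjusted p = 0.0111), with losses for GPH1 (-3.23 ± 0.52), GLC3 (-2.65 ± 0.37) and hexokinase HXK1 (-2.99 ± 0.56). The aquaglyceroporin gene AQY3 (-2.86 ± 0.42) and the kinase gene KIN82 (-2.71 ± 0.42) completed the 5 largest falls. Occupancy rose most for RPL22B (1.92 ± 0.41), the cell cycle regulator ACM1 (1.83 ± 0.40), histone HTB1 (1.65 ± 0.36), RPS9A (1.52 ± 0.33, uncertain) and VIK1 (1.49 ± 0.31). No change passed for HSP30 (0.14 ± 0.89), HSP12 (-0.01 ± 0.45), HSP104 (-0.15 ± 0.56), HSP26 (-0.30 ± 0.69), SSA4 (-0.58 ± 0.81), TSL1 (-0.89 ± 0.44), PGK1 (-0.23 ± 0.56), CIT1 (0.00 ± 0.32) or RPL3 (-0.14 ± 0.38), with errors too wide to exclude a 2-fold change for HSP30, HSP104, HSP26, SSA4, TSL1 and PGK1.

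Occupancy passed as higher for 14 and lower for 53 of 5018 genes, and with library size alone for 4 and 48. Of the 53 that fell, 51 had higher polyA RNA, with a median footprint change of 0.26. Of the 157 mRNAs that rose at least 4-fold, 136 had an occupancy change below 0 and 26 passed as lower (median -1.10), and of the 119 that fell at least 2-fold, 118 lay above 0 and 2 passed (median 0.92). Those sets were chosen on the polyA libraries that are also the denominator of occupancy, so part of this opposition comes from their shared noise.

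Glycogen and trehalose genes lost occupancy in 5 of 19 cases with all 19 changes below 0 (13 adjusted over the list alone), TCA cycle genes in 3 of 16 (5), with SDH4 (-1.59 ± 0.27) and SDH3 (-1.46 ± 0.23), hexose uptake in 2 of 14 (5), with the uncertain HXT7 (-2.46 ± 0.43), Msn2/Msn4 genes in 2 of 26 (5), GAD1 (-2.09 ± 0.36) and DCS2 (-1.94 ± 0.46), Hsf1 targets in 1 of 18 (1), HSP42 (-2.67 ± 0.61), and respiratory subunits in 0 of 30 (0). Camera called these 6 lists lower (adjusted p = 1.85e-15, 0.00012, 0.00014, 2.59e-05, 0.0038 and 0.0128), a call lost with an estimated correlation (adjusted p = 0.0775, 0.493, 0.209, 0.493, 0.696 and 0.696). Fry called only glycogen and trehalose (fry adjusted p = 0.0077) and hexose uptake (fry adjusted p = 0.0404) lower. With the replicate block 8 glycogen and trehalose, 5 TCA cycle, 4 Msn2/Msn4 and 2 respiratory subunit genes passed as lower. Ribosome biogenesis genes had all 62 changes above 0 with 1 passing (10 adjusted over the list alone), SSF1 (1.04 ± 0.20, uncertain), histones 9 of 10 above 0 with HTB1 passing (5), and cell cycle genes 19 of 22 above 0 with 0 passing (2 higher and 1 lower). With the block 5 ribosome biogenesis genes and 3 histones passed as higher, and 1 cell cycle gene as higher and 1 as lower. Camera called these 3 higher (adjusted p = 6.91e-12, 0.00028 and 0.0018), again lost with an estimated correlation (adjusted p = 0.493, 0.493 and 0.631).

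The other heat shock genes had 1 of 15 lower (1), SSE2 (-1.95 ± 0.45), and glycolysis 2 of 17 (2), PYK2 (-1.71 ± 0.39) and the uncertain TDH1 (-2.59 ± 0.47). Neither was called by camera (adjusted p = 0.0559 and 0.0769), and both were with the replicate block (adjusted p = 0.0212 and 0.0212), a call lost there with an estimated correlation (adjusted p = 0.738 and 0.738). Gluconeogenesis had 1 of 12 lower, the activator ADR1 (-1.71 ± 0.35; 1 higher and 1 lower adjusted over the list alone), and cytosolic ribosomal proteins 2 of 136 higher (2 higher and 1 lower). No member passed in the remaining lists, 33 amino acid synthesis (0 over the list alone), 14 ER chaperone (0), 22 ergosterol (1 higher, and a median that turns negative with library size alone), 56 mitochondrial ribosomal protein (1 higher and 2 lower), 20 P-body (0), 32 proteasome (0) and 32 translation factor genes (0), and camera called none of these 9 lists. Library size alone moves the median occupancy change of all genes from 0.05 to -0.03. With the block 1 gluconeogenesis gene passed as higher and 1 as lower, and 2 cytosolic ribosomal protein genes as higher and 1 as lower. Of the remaining lists 1 mitochondrial ribosomal protein gene passed as higher and 2 as lower, 1 each of the ergosterol and translation factor genes as higher, and 1 each of the amino acid synthesis, P-body and proteasome genes as lower.

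**Figure D3:**
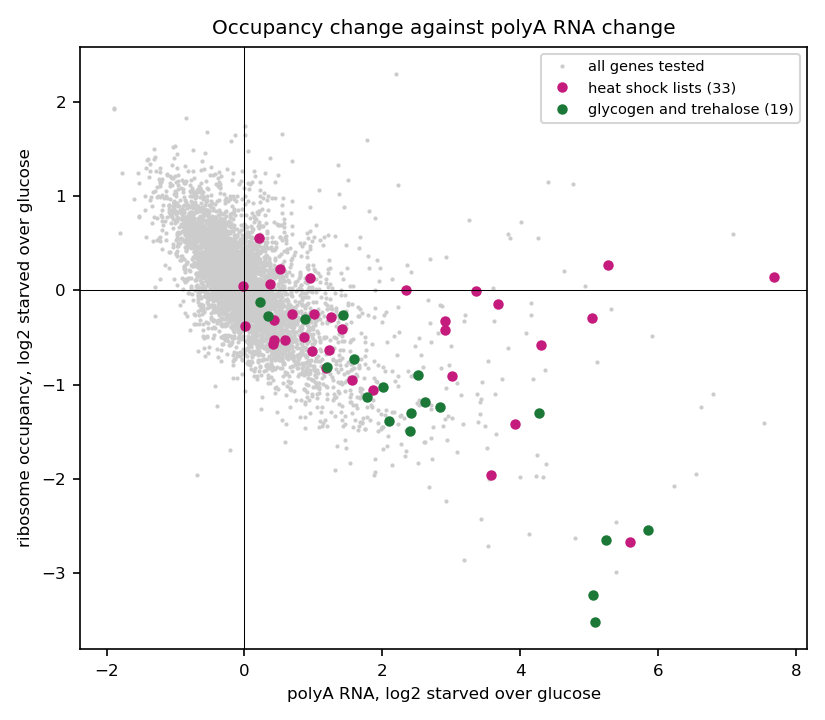
Change in ribosome occupancy against change in polyA RNA (both log2, starved over glucose) for 5018 genes (grey), the 33 heat shock genes (magenta) and 19 glycogen and trehalose genes (green). All 19 glycogen and trehalose genes lie below 0 on the vertical axis, as do 14 of 18 Hsf1 targets and 11 of 15 other heat shock genes.

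With the replicate block 94 genes passed as higher and 152 as lower, and without both BY4741 footprint libraries numbered 2 the counts were 92 and 110. No gene passed in BY4741 alone or against total RNA, and EY0690 alone gave 179. With edgeR 139 of 4785 genes had an unadjusted p under 0.05 in BY4741 alone, fewer than no change would give. Against BY4741 total RNA, with 1 library per condition, the spread came from the footprint libraries alone. Leaving out 1 library gave 20 to 225 genes. In BY4741 the total was 225 and 166 without the first and second starved footprint libraries, 41 and 26 without the first and second glucose polyA libraries, and 26 and 172 without the starved ones. In EY0690 it was 32 and 30 without the second glucose and second starved footprint libraries, 29 and 38 without the first and second glucose polyA libraries, and 20 and 32 without the starved ones.

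A planned contrast set the heat shock lists against the glycogen and trehalose list, the question being, as far as the study is known, whether mRNAs that accumulate together are translated alike. The 33 heat shock genes had a mean occupancy change of -0.53 and the 19 glycogen and trehalose genes of -1.33, a difference of 0.80 ± 0.24 (SD over 4 pairs of strain and replicate number) that was positive in 4 of 4 pairs, at 0.52, 0.75, 0.85 and 1.09. The exact two-sided permutation test over 1296 arrangements gave p = 0.0756 (the smallest possible is 0.0015), which misses the threshold, and exact sign flips of the 4 pairs gave p = 0.125, the smallest that 16 arrangements allow. Arrangements that swap condition in footprints alone or in polyA RNA alone still hold real responses and are not arrangements without a change. The permutation p thus asks whether neither assay responded, not whether occupancy changed alike, so missing the threshold does not decide the contrast. By the same exact permutation test p fell to 0.0417 without the first glucose BY4741 footprint library (0.95), to 0.0154 without the second starved one (1.02) and to 0.0185 without both of those numbered 2 (0.88). By the exact permutation test it did not pass without any of the other 14 libraries (p from 0.0525 to 0.262), without every BY4741 library numbered 2 (0.75, p = 0.0556) or with the median over members (0.60, p = 0.327).

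**Figure D4:**
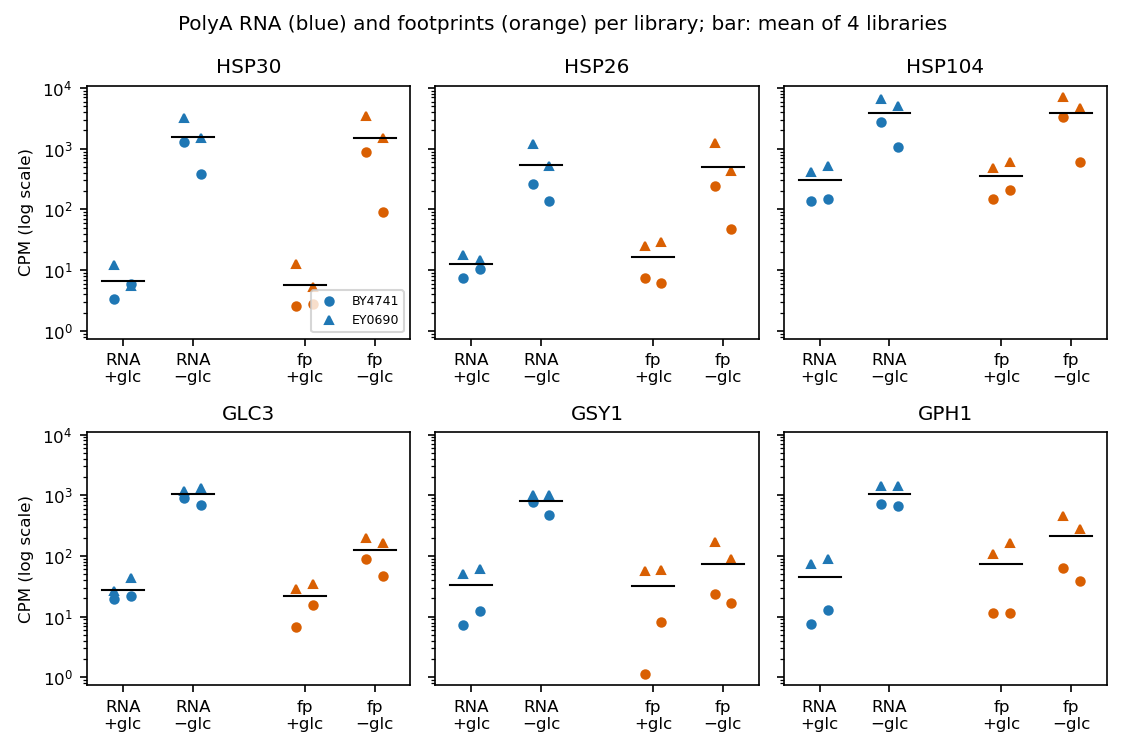
CPM on a log axis of 3 heat shock genes and 3 glycogen genes in each polyA (blue) and footprint (orange) library with (+glc) and without (−glc) glucose, with BY4741 as circles, EY0690 as triangles and the mean of 4 libraries as a bar. GSY1 polyA RNA rose by 5.08 on the log2 scale with a 2.84-fold footprint change that did not pass (edgeR adjusted p = 0.0807, and 0.0187 with the replicate block). HSP30 rose by 7.68 in polyA RNA and 7.77 in footprints.

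The fourth comparison asks whether polyA selection shaped the RNA response. In BY4741 total RNA, with 1 library per condition and so no replicate check, HSP30 changed by 5.98 against 7.08 in polyA RNA, GSY1 by 6.10 against 5.91, GLC3 by 5.59 against 5.24 and GPH1 by 4.37 against 6.05. In the pooled EY0690 RNA the authors' pooled values gave 6.79 against 7.89 for HSP30 and 3.67 against 4.13 for GSY1. There HXT7 (uncertain) changed by 3.12 against 4.93, HXK1 by 3.52 against 4.57, and PGK1, which passed as higher in polyA RNA, by -0.09 against 0.81. Of 5310 genes none differed by edgeR (112 at an unadjusted p under 0.05) and 1 responded less upward in total than in polyA RNA by DESeq2, with a median SE of 0.45. The spread in this test comes from the polyA libraries alone. Camera called the response of the gluconeogenesis list less upward in total than in polyA RNA (12 of 16 differences, total minus polyA, below 0, adjusted p = 0.00071, and 0.538 with an estimated correlation). It called that of ergosterol synthesis more upward in total than in polyA RNA (18 of 22 above 0, adjusted p = 0.0092, and 0.538 with an estimated correlation). No member of any of the 20 lists passed over all genes or adjusted over the list alone, and none of the other 18 lists was called.

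The difference between the strains was tested over both conditions together. Highest in EY0690 over BY4741 were the regulator DAL80 (6.49 ± 0.52), the proline permease PUT4 (6.32 ± 0.28), SUE1 (5.37 ± 0.32), the general amino acid permease GAP1 (4.94 ± 0.25) and the ammonium transporter MEP2 (4.79 ± 0.29). GAP1 stood at 55.7 and 90.5 CPM in glucose BY4741 and at 1869 and 1774 CPM in glucose EY0690. Higher in BY4741 were ZPS1 (-6.14 ± 0.44 as EY0690 over BY4741), the sulfate permease SUL1 (-5.10 ± 0.82), RPL41A (-4.11 ± 0.85, uncertain), CHA1 (-3.56 ± 0.38) and the sulfate assimilation gene MET14 (-3.17 ± 0.41). By edgeR 1071 genes were higher in EY0690 and 900 in BY4741 of 5304. The labels give 1 strain of each kind, so strain cannot be told apart from any other difference between the 2 sets of cultures. Both strains were aligned to 1 genome build, made from the background of BY4741. Whether sequence differences of EY0690 lowered its counts was not tested.

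Whether the response to glucose withdrawal differed between strains was tested by its own term. PRM7 (3.94 ± 0.56), the GABA permease gene UGA4 (2.80 ± 0.45) and malate dehydrogenase MDH2 (2.47 ± 0.40) responded more upward in EY0690, and the purine synthesis gene ADE17 (-3.18 ± 0.56), cyclin PCL1 (-2.86 ± 0.44), alcohol dehydrogenase ADH4 (-2.43 ± 0.42), the repressor YOX1 (-2.33 ± 0.39), YRO2 (-2.11 ± 0.32) and cyclin CLN1 (-1.99 ± 0.34) less upward, with adjusted p from 0.0269 to 0.0379 by edgeR. CLN1 lies outside the naming rule and was named after its value was seen. ADE17 lost its call with the replicate block (adjusted p = 0.0885 by edgeR). DESeq2 called 15 and 22 genes. Without 1 library edgeR called 0 (first glucose BY4741, first glucose EY0690 or first starved EY0690), 1 (second glucose EY0690), 2 (second glucose BY4741), 17 (second starved EY0690), 25 (first starved BY4741) or 73 genes (second starved BY4741). For footprints no gene differed by edgeR (152 at an unadjusted p under 0.05), DESeq2 called 3, the replicate block 5 higher and 7 lower, and leaving out the second starved BY4741 library gave 28.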

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

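The split of both assays alike was a test chosen only after the results had been seen, as were the libraries left out together and the deciding reference of the list contrast. Other splits of the same libraries were counted for each comparison of at least 3 libraries per side. For polyA RNA 1 of 34 splits, the real one, gave 2103 genes and the highest other gave 0, for footprints 1 of 34 gave 160 and the highest other 38, and for the strain difference 1 of 34 gave 1971 and the highest other 0. No other split reached the real count for these 3, but each other split leaves part of the real difference in its residual spread, which lowers its count. Of the 34 splits 8 part the 4 pairs of numbered libraries as the real split by condition does, and the highest other count among those was 0 for polyA RNA and 0 for footprints. For the strain difference 3 splits part the pairs as the real one does. With the libraries paired, so few splits cannot exclude chance. For occupancy, 9 of 100 splits drawn separately within each assay gave at least the real 67 genes and the highest other gave 759. Of the 50 that part all 8 pairs, 8 were as large. Of the 8 other splits, 4 set footprints and polyA RNA in opposite directions of the condition, as 15 drawn splits did, and 4 split polyA RNA by condition and footprints evenly, as 5 did. In such splits the assay by split term holds the real condition response of polyA RNA, at least in part. They are not splits without a change, so the count of 9 of 100 neither excludes chance nor speaks for it. When both assays of a strain, condition and number took the same side, 1 of 34 splits, the real one, gave 67 genes and the highest other gave 0. There too each other split leaves part of the real difference in its residual spread, which lowers its count. Only 8 of these 34 splits part all 8 pairs, so they cannot exclude chance either.

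The polyA response of 9 genes stood out because it differed between the strains by a test of that difference. As EY0690 minus BY4741 these were PRM7 (3.94), UGA4 (2.80), MDH2 (2.47), CLN1 (-1.99), YRO2 (-2.11), YOX1 (-2.33), ADH4 (-2.43), PCL1 (-2.86) and ADE17 (-3.18). MDH2, a malate dehydrogenase of gluconeogenesis, changed by -0.28 in BY4741 and 2.14 in EY0690, ADE17 by 2.19 and -1.01, and PCL1 by -0.77 and -3.67. No explanation for these was tested. The initiation region, which enters only the alternative with both regions summed, held more of the footprint reads (8.16% to 14.5%) than of the RNA reads (3.37% to 4.79%), with 8.16% as the lowest footprint share.

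The first pattern weighed is that the BY4741 footprint libraries numbered 2 lie close to polyA RNA (0.946 and 0.942 across genes). Thinning all 8 footprint libraries to 697736 counts kept a share of 0.852 of the gap to the next library, which argues against greater depth as the cause. GCN4 and HAC1, mRNAs held from translation in glucose, had a mean log2 footprint over polyA ratio of -0.71 in the second glucose BY4741 library against -1.56, -2.78 and -3.58 in the other glucose libraries. That met the prediction set beforehand for untranslated mRNA fragments, a mean higher than in each of the other glucose libraries. The prediction is not taken as deciding, since every ratio lies nearer 0 in a library close to polyA RNA (SD across genes 0.61 against 0.98 to 1.16). This limit was not part of the prediction, so untranslated fragments stay open. The labels do not say which libraries were purified by cushion and which by gradient, so that difference stays open and untested, and no biological explanation was tested.

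The second pattern is the smaller response in the starved BY4741 libraries numbered 2. If glucose-grown material were mixed in, 1 share should fit the genes that rise and those that fall. The 23 polyA genes rising over 16-fold in EY0690 gave a share of 50.5% (quartiles 26.7% and 63.6%), which predicts a median fall within 0.075 of the observed -0.52 over 229 genes, and the 7 footprint genes gave 79.1%, a prediction within 0.013 of -0.11 over 115 genes, while the same scaling of every log2 change would give -0.96 and -0.26. A mixture lowers every induced mRNA, but 3 of the 23 polyA genes and 0 of the 7 footprint genes were higher in the second starved library than in the first (JEN1 polyA RNA stood at 662 against 315 CPM), so for polyA RNA a mixture stays undecided, while the footprint values are consistent with one or with cells that had not yet responded. The calculation takes the BY4741 libraries numbered 1 as unmixed, that assumption and the count of genes that were higher were added after the values were seen, and no biological explanation was tested.

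The third pattern is that glycogen and trehalose mRNAs lost more occupancy than heat shock mRNAs, a difference of 0.80 that itself missed the threshold (p = 0.0756, exact permutation test). By the same exact permutation test it was 0.71 (p = 0.139) with BY4741 total RNA and the pooled EY0690 RNA as the reference and 0.42 (p = 0.833, smallest possible 0.167) with BY4741 total RNA alone, where the BY4741 pairs with polyA RNA gave 0.52 and 0.75, and the pooled reference and a margin of 1 SD over pairs, though not the bound of 50% of 0.80, were chosen after these values were known. It was 0.88 without the BY4741 footprint libraries numbered 2, which argues against those libraries as the cause. In 10000 draws of genes matched on polyA change the glycogen list's mean lay at percentile 0.02 and that of the heat shock lists at 87.2. In these libraries the glycogen list thus lost more than genes with a like mRNA rise, although matching on noisy values leaves some regression to the mean. The draws take genes as independent, while the estimated correlation within the glycogen list was 0.27 in occupancy. The percentile is then too extreme, and the size of the mRNA rise alone stays open. The permutation p does not test equal occupancy change alone, and exact sign flips of the pairs could give no p under 0.125. Neither can exclude chance, which stays open, and no biological explanation was tested.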

How the results depend on the processing

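Both regions summed, the pooled EY0690 reference and the omission of libraries together were alternatives chosen after the data had been seen. The polyA count of 2103 stayed within 1.5 times under every other alternative run, but was 381 in BY4741 alone, against 1588 in EY0690 alone with as many libraries, and 218 with BY4741 total RNA. The footprint count of 160 became 299 with DESeq2, 1 in BY4741 and 427 in EY0690 alone, 429 with the replicate block, 273 with both regions summed and 579 without the BY4741 footprint libraries or every BY4741 library numbered 2. The occupancy count of 67 became 200 with DESeq2, 0 in BY4741 and 179 in EY0690 alone, 246 with the replicate block, 20 with both regions summed, 202 and 210 without those libraries, 0 against BY4741 total RNA and 0 against total and pooled RNA, where edgeR gave 258 of 4882 genes at an unadjusted p under 0.05, about the share that no change would give. The total and pooled RNA had 1 library per strain and condition, and against both 66 of the 66 main occupancy calls tested kept their sign. The footprint libraries are the same in both fits. The strain by condition counts of 9 and 0 became 37 and 3 with DESeq2, and that of footprints 12 with the replicate block. The count for polyA selection went from 0 to 1 with DESeq2. The lists called went from 12 to 4 for polyA RNA, 9 to 0 for footprints, 9 to 0 for occupancy and 2 to 0 for selection with an estimated correlation, and with fry to 5, 2 and 0 for the last 3. For polyA RNA fry called 13 lists, among them all 12 of camera in the same direction. The list contrast was 0.88 and passed (p = 0.0185, exact permutation test) without the BY4741 footprint libraries numbered 2. HHF1 turned to 0.20 with BY4741 total RNA. The cause was not tested.

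Leaving out each library in turn gave 1573 to 2340 genes for polyA RNA, 80 to 487 for footprints, 20 to 225 for occupancy, 1556 to 2269 for the strain difference, 0 to 73 and 0 to 28 for the strain by condition terms, and 0.57 to 1.04 for the list contrast, and the lone library left in a group is assumed to vary like the others. Footprints gave 103 without the first glucose BY4741, 487 without the second starved BY4741, 88 and 87 without the first and second glucose EY0690 and 80 and 102 without the first and second starved EY0690 library. Occupancy gave 225 and 166 without the first and second starved BY4741 and 32 and 30 without the second glucose and second starved EY0690 footprints, and, without polyA libraries, 41, 26, 26 and 172 in BY4741 (glucose 1 and 2, starved 1 and 2) and 29, 38, 20 and 32 in EY0690. The polyA strain by condition term gave 0, 2, 25 and 73 in that BY4741 order and 0, 1, 0 and 17 in EY0690, and that of footprints 28 without the second starved BY4741 library. The list contrast passed without the first glucose (0.95) or second starved (1.02) BY4741 footprint library.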

Other observations

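The nitrogen and sulfur lists below were written, and all tests in this part chosen, only after the leading strain differences had been seen, so they are not independent evidence of a direction. Of 18 measured genes for uptake and use of poorer nitrogen sources, 15 were higher in EY0690 polyA RNA and none in BY4741 by edgeR, with a median of 1.98 on the log2 scale (2.45 among the libraries numbered 1 and 1.87 among those numbered 2). Footprints of 16 of them had a median of 1.88. Of 18 genes of sulfate assimilation and methionine synthesis, 15 were higher in BY4741 and 1 in EY0690, with a median of -1.66 as EY0690 over BY4741 (-1.53 and -1.74) and a footprint median of -2.20 over 16 genes. SUL1 had 1139 polyA counts over the BY4741 libraries and 8 over the less deeply sequenced EY0690 libraries. The fitted difference, which scales for depth, was -5.10 ± 0.82 (SE) on the log2 scale.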
